A study of Mus musculus with 8 samples.

How the data were processed

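RNA of Thy1+ and cKit+ spermatogonia from C57BL/6 testes at postnatal day 7 was measured in 8 libraries, 2 for each of 4 groups: Thy1 control, Thy1 dKO, cKit control and cKit dKO. Per the labels' protocols, RNA was purified with an RNeasy micro kit, amplified to double-stranded cDNA (NuGEN Ovation v2), made into Nextera XT libraries and sequenced on an Illumina HiSeq. Per the submitters' processing notes, reads were aligned with STAR 2.4.2a to mm10. The counting tool, its strand setting and its filters are not stated, so overlapping and antisense genes cannot be told apart by strand.

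Each deposited table lists 26099 RefSeq transcript entries under 23343 gene symbols, with chromosome, start, end and strand, a column of read counts and a column of RPKM values. The deposited counts are whole numbers with no normalization, per the file headers and their values. The deposited RPKM values were computed by the authors per kilobase of transcript and relative to the reads of the library, per the file headers. Of the symbols, 2060 have several entries (2756 repeated ones in all). Among 769 symbols with 2 entries of at least 100 counts each, 33 had counts within 1% of each other, as if the same reads were counted for both; Kit is one of them. Counts were summed per symbol, so such genes may hold some reads more than once. Coordinates are as deposited, in mm10, and starts match 1-based annotation starts. Paralogs with shared sequence, such as the protocadherin clusters, could have their reads split by the counting and are uncertain.

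Library totals ran from 6763908 to 10976869 counts, and 27.3% to 33.1% of the entries of a library had 0 counts. Amplified libraries carry no molecular identifiers, so floors cover counting error only. A fold against a group with 0 counts in both libraries was computed against a floor of 3 counts over the group. The counts of the other group were taken as they stand, so a fold given as at least a value bounds only the side at 0. Replicate pairs spread more than counting error, with a chi-square over degrees of freedom of 6.30 (Thy1 control), 4.42 (Thy1 dKO), 13.4 (cKit control) and 10.4 (cKit dKO). Correlations of log2 CPM across genes were 0.957 to 0.980 within groups, and every library correlated best with its own replicate. The first principal component took 49.1% of the variance and separated the populations; the third, with 10.1%, separated the 2 cKit dKO libraries.

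The design, the gene lists, the rule for named genes and the other settings to be run were fixed before the data were examined. Gene tests used edgeR 4.0.16 in R 4.3.3: counts summed per symbol, filterByExpr by group (14907 genes kept), TMM scaling, 1 mean per group with 4 residual degrees of freedom, glmQLFit and glmQLFTest (two-sided), and Benjamini-Hochberg adjustment with a threshold of 0.05. The common dispersion was 0.0222 and the prior degrees of freedom 11.0. All 8 libraries entered each fit, since 2 libraries per group give little information on the spread. Each fit thus pools the spread over groups, although replicates spread more in cKit than in Thy1. Pooling can make p-values too large in Thy1 and too small in cKit. Comparisons were dKO against control in Thy1 and in cKit, cKit against Thy1 in control and in dKO, and the difference of the dKO effects. Standard errors of the change of a gene are the absolute log2 fold change over the square root of the F statistic. Those of a median over genes come from a bootstrap over the genes. They treat genes as independent and do not measure the spread between samples. CPM values use the TMM-scaled library sizes.

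The 26 lists were PRC1 subunits, PRC2 subunits, Hox genes, somatic developmental transcription factors, undifferentiated and differentiating spermatogonia, meiotic prophase, piRNA pathway, core germ cell identity, late spermatogenesis, oocyte and granulosa, Sertoli, Leydig, peritubular and stromal, endothelial, macrophage, T cell, mast cell and erythroid markers, S phase, G2 and M phase, CDK inhibitors and p53 response, DNA methylation enzymes, imprinted genes, immediate early and heat shock genes, and WNT, BMP, FGF and hedgehog ligands and antagonists. Lists with at least 3 tested members (25) were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Of the lists tested, 12, 15, 8 and 13 passed in Thy1 dKO, cKit dKO, control cKit against Thy1 and dKO cKit against Thy1. With an estimated correlation 0 passed in each, with smallest adjusted p = 0.29, 0.13, 0.079 and 0.15. Fry, which asks whether the genes of a list move on balance one way without comparing it with other genes, passed 0, 17, 13 and 22 lists.

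Named genes were 12 genes in every comparison (Ring1, Rnf2, Thy1, Kit, Stra8, Zbtb16, Gfra1, Dazl, Ddx4, Cdkn2a, Gata4 and Wt1), per comparison the 10 higher and 10 lower genes of largest change among those with an adjusted p under 0.05, a mean log2 CPM of at least 3, and both libraries of one group above both of the other, and up to 4 members per list by smallest p. Predicted genes and small RNAs were counted but not named. Of the genes picked by this rule, 1 is not reported here. Genes named as shared between comparisons were picked among these.

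On simulated data with 100 genes changed 2-fold and 100 changed 4-fold, the test recovered 55% and 86% of them in Thy1 (14569 genes tested), 56% and 86% in cKit (14571), 48% and 80% between the controls (14548), 48% and 79% between the dKO groups (14543), and 35% and 71% for the difference of effects (14566). Unchanged genes called numbered 9, 8, 10, 7 and 13. A list shifted by 0.5 on the log2 scale in simulated cKit libraries was found by camera, by camera with an estimated correlation and by fry. Genes were simulated independently, so this does not show how these tests behave where the genes of a list vary together.

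Alternatives were RLE size factors, library totals, no filter, a CPM filter (at least 1 in 2 libraries), DESeq2 1.42.0, limma-voom, limma on log2 RPKM with a pseudocount of 1 or 0.1, a 2-fold minimum, entries not summed, the replicate number as a block, only the 4 libraries compared, and each library left out in turn, where the lone library of a group is assumed to vary like the other groups. Chosen after seeing the data were scaling on the core germ cell and piRNA lists (median of ratios), leaving out Rn45s, and leaving out replicate 1 of both control groups (cKit control replicate 1 has a record number apart from the others, and Thy1 control replicate 1 has more stromal transcripts). No group has 3 libraries, so samples were not regrouped and no test for outlying samples was made.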

Results

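RNA was sequenced from Thy1+ and cKit+ spermatogonia of testes from C57BL/6 mice at postnatal day 7, labelled PRC1ctrl (control) or PRC1dKO (dKO). PRC1, Polycomb repressive complex 1, is a chromatin complex that ubiquitinates histone H2A and keeps many developmental genes silent. Thy1 sorting enriches undifferentiated spermatogonia, and Kit marks spermatogonia that have begun to differentiate. There were 4 groups of 2 libraries each: Thy1 control, Thy1 dKO, cKit control and cKit dKO. Total counts were 7417665 and 8362701 in the Thy1 control libraries (replicates 1 and 2), 8755623 and 7135129 in the Thy1 dKO libraries, 10976869 and 7858587 in the cKit control libraries, and 6763908 and 6798003 in the cKit dKO libraries. Rn45s, the ribosomal RNA precursor, took 8.42% to 13.6% of the counts of a library. The labels do not spell out the control genotype, the deleted genes, or whether replicates came from different animals. Where they did not, the p-values given here measure only the spread between these samples.

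Ring1 and Rnf2, the E3 ligase subunits of PRC1, did not pass the test in the libraries labelled dKO. Rnf2 (mm10 chromosome 1, 151469406 to 151500823) stood at 112 ± 12.3 CPM (counts relative to library size, SD, n = 2) in Thy1 control, 127 ± 1.68 in Thy1 dKO, 135 ± 15.1 in cKit control and 138 ± 4.73 in cKit dKO. Ring1 (chromosome 17, 34020792 to 34024680) stood at 2.93 ± 0.32 CPM, 3.88 ± 1.83, 4.87 ± 0.51 and 8.04 ± 5.61 CPM in the same order, low in every group. The log2 fold change of Rnf2 in dKO was 0.18 ± 0.13 (SE) in Thy1 and 0.02 ± 0.12 in cKit, with edgeR adjusted p = 0.56 and 0.91. That of Ring1 was 0.39 ± 0.54 and 0.73 ± 0.50, with edgeR adjusted p = 0.81 and 0.30. Without cKit dKO replicate 2 the Ring1 change in cKit was 1.34 and passed the test (edgeR adjusted p = 0.040), and without replicate 1 it was -0.20. In Thy1 the Ring1 change was 0.82 without Thy1 dKO replicate 1 and -0.17 without replicate 2, neither past the test. Counts over a whole gene need not fall when only some exons are deleted, so these levels do not check the labels, and the groups are called the libraries labelled dKO or control.

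**Figure D1:**
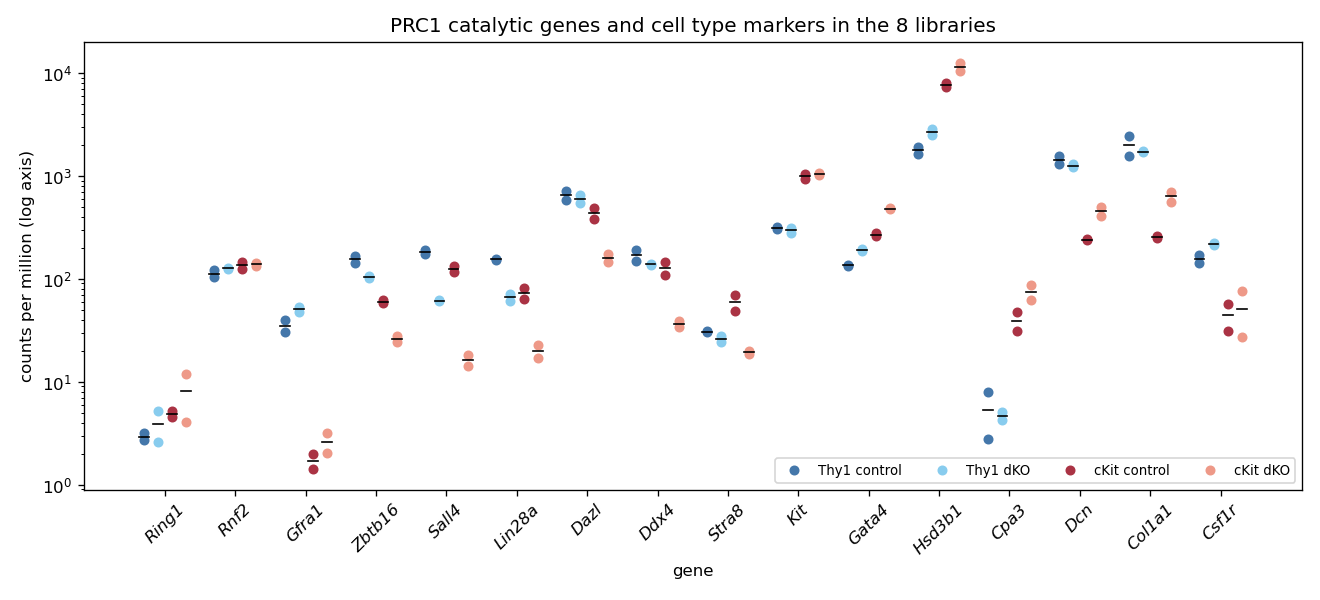
CPM (log axis) of the PRC1 ligase genes and of cell type markers in each of the 8 libraries; points are libraries and bars the mean of 2. Sall4 fell from 182 to 61.2 CPM between the Thy1 groups and from 125 to 16.2 CPM between the cKit groups, Dazl stood at 159 CPM in cKit dKO against 433 in control, and Col1a1 at 631 against 254.

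In the Thy1 libraries labelled dKO, transcripts of Sall4 and Lin28a fell and those of Nefm rose. Sall4, a zinc finger transcription factor of stem and germ cells (chromosome 2, 168748332 to 168767201), was at 61.2 ± 1.32 CPM (SD, n = 2) against 182 ± 12.1 in Thy1 control, a log2 fold change of -1.57 ± 0.13 (SE; edgeR adjusted p = 7.3e-05). Lin28a, an RNA-binding protein that blocks let-7 microRNA maturation (chromosome 4, 134003330 to 134018816), was at 65.9 ± 6.44 CPM against 155 ± 3.28, a change of -1.23 ± 0.15 (edgeR adjusted p = 0.0027). Nefm, the medium neurofilament subunit (chromosome 14, 68119545 to 68125004), rose from 14.04 ± 0.89 to 68.3 ± 1.86 CPM, by 2.28 ± 0.20 on the log2 scale (edgeR adjusted p = 7.3e-05).

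The question of this comparison was which genes differ between the libraries labelled dKO and control in the Thy1+ population. Of 14907 genes tested, 93 changed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, 54 higher and 39 lower, and 2059 had an unadjusted p under 0.05. With scaling on germ cell genes, an alternative chosen after seeing the data, 138 were higher and 5 lower, and with limma on the deposited RPKM values the numbers were 10 and 14. Among those that changed at least 2-fold, 16 were higher and 19 lower. Among called genes at a mean log2 CPM of at least 3, with both libraries of a group above both of the other, the largest rises after Nefm were in Tmprss13, a membrane serine protease (2.14 ± 0.41), Npffr2 (1.64 ± 0.34) and Prokr2 (1.28 ± 0.25), both neuropeptide receptors, Epha2, an ephrin receptor (1.54 ± 0.30), and Bmp5, a BMP ligand (1.17 ± 0.25). Stk32a, Gpr56, Ptprb and Leprel1 rose by 1.001 to 1.15. Within the same limits the largest falls beside Sall4 and Lin28a were in Oasl2, an interferon-induced gene (-1.89 ± 0.32), Sall1, a relative of Sall4 (-1.69 ± 0.32), and Ascl2, an imprinted bHLH factor (-1.41 ± 0.27). Aldoc, Pramef12, Cd274, Chtf18 and Mns1 fell by 1.09 to 1.27. Of the genes named in every comparison, Gata4 rose (0.49 ± 0.10), while Zbtb16 (-0.58), Gfra1 (0.52), Kit (-0.06), Stra8 (-0.23), Dazl (-0.11), Ddx4 (-0.31) and Wt1 (-0.12) did not pass the test. Zbtb16 had an edgeR adjusted p of 0.055 and passed without either cKit dKO library.

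Among the lists fixed in advance, the undifferentiated spermatogonia list was lower in Thy1 dKO (median log2 -0.52; camera adjusted p = 6.3e-06, and adjusted p = 0.29 with an estimated correlation). Of its 30 tested members 4 fell, Sall4, Lin28a, Mcam (-0.77 ± 0.13) and Neurog3, a bHLH factor of progenitors (-3.93 ± 0.72), and 26 did not pass. Adjusted over the list alone, 3 were higher and 10 lower. The core germ cell list (median -0.31; 1 of 22 lower, camera adjusted p = 2.4e-05) and the piRNA list (median -0.37; camera adjusted p = 9.1e-06) were lower as sets, with adjusted p = 0.43 and 0.40 with an estimated correlation. Both medians were above 0 after germ cell scaling, which sets them near 0 by construction. In the piRNA list Tdrd9, a helicase that silences transposons, fell (-1.03 ± 0.20). Tdrd6, a chromatoid body protein with 0 counts in both Thy1 controls, was at least 16.9-fold higher against a floor of 3 counts over the group. Adjusted over the list alone, 1 core member was higher and 1 lower, and 1 piRNA member was higher and 4 lower. The S phase (median -0.26; 0 of 26 members past the test, 1 lower adjusted over the list alone) and G2 and M phase lists (median -0.16; 0 of 25, 2 lower adjusted over the list alone) also passed camera (adjusted p = 2.4e-05 and 0.0015, and adjusted p = 0.43 and 0.59 with an estimated correlation). Germ cell scaling turned both medians positive, and the G2 and M phase list did not pass without Thy1 control replicate 2. The differentiating list (median -0.05; 0 of 14 past the test) and the meiotic list (0.04; 0 of 35) did not pass camera (adjusted p = 0.64 and 0.89), and each median changed sign without a Thy1 library.

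Markers of other testis cells moved beside these germ cell genes. The Leydig list was higher (median 0.46; 3 of 13 members rose, adjusted over the list alone 7 higher and 2 lower; camera adjusted p = 3.0e-05, and adjusted p = 0.40 with an estimated correlation). Its risers were the steroid enzyme Hsd3b1 (0.58 ± 0.11), Akr1cl (0.68 ± 0.14) and the nuclear receptor Nr5a1 (0.64 ± 0.11), which is also a Sertoli list member. The Sertoli list (median 0.43; 2 of 26 rose, Nr5a1 and Gata4, and 3 adjusted over the list alone), the endothelial list (median 0.62; 1 of 15, Cdh5 at 0.52 ± 0.10, and 6 adjusted over the list alone) and the macrophage list (median 0.48; 0 of 17, and 0 adjusted over the list alone) had camera adjusted p = 2.6e-04, 9.1e-06 and 0.0024, and adjusted p = 0.29, 0.29 and 0.64 with an estimated correlation. The peritubular and stromal list was lower (median -0.19; 0 of 21 past the test, adjusted over the list alone 1 higher and 4 lower; camera adjusted p = 0.025, and adjusted p = 0.67 with an estimated correlation). Its median turned positive after germ cell scaling and without Thy1 control replicate 1, and the list did not pass without that library or Thy1 dKO replicate 1.

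Lists of developmental genes also passed camera upward at the preset correlation, while fry passed 0 of the 25 lists in Thy1 dKO. With Sertoli and endothelial markers also higher, a larger share of somatic RNA cannot be told apart from a rise within germ cells. No Hox gene passed over all genes (0 of 29; Hoxd9 0.65 ± 0.18, Hoxc13 2.96 ± 0.85). Adjusted over the list alone 6 were higher and 1 lower, and the list had a median of 0.53 (camera adjusted p = 0.035, and adjusted p = 0.29 with an estimated correlation). Of 57 somatic developmental transcription factors 2 rose, the homeobox gene Dlx3 (1.92 ± 0.37) and Gata4. There 6 were higher and 1 lower adjusted over the list alone (median 0.29; camera adjusted p = 0.0032, and adjusted p = 0.29 with an estimated correlation). The Hox list did not pass in 5 of 11 other settings, and the transcription factor list not without Thy1 control replicate 2. Bcor, of a PRC1 variant, rose (0.92 ± 0.13), alone among 22 PRC1 subunits (2 higher and 3 lower adjusted over the list alone). Mtf2, a PRC2 partner, fell (-0.66 ± 0.13), alone among 11 PRC2 subunits (also 1 adjusted over the list alone). Neither list passed camera (adjusted p = 0.57 for both).

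The count of 93 depended on single libraries: it was 8 without Thy1 control replicate 1, 16 without control replicate 2, 3 without Thy1 dKO replicate 1 and 3 without replicate 2. It was 392 and 400 without cKit dKO replicate 1 or 2, and 7 without replicate 1 of both control groups. Sall4 passed without any one of the 4 Thy1 libraries (edgeR adjusted p = 0.0016 to 0.0076). Lin28a did not without either dKO library (edgeR adjusted p = 0.051 and 0.11). Nefm passed without any one of them, Mcam, Oasl2 and Pramef12 passed without 1 of them, and the other Thy1 calls named here were lost without each.

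In the cKit libraries labelled dKO, germ cell and cell cycle transcripts fell together while transcripts of somatic genes rose. Sall4 dropped from 125 ± 10.3 to 16.2 ± 2.79 CPM (SD, n = 2), a log2 fold change of -2.94 ± 0.15 (edgeR adjusted p = 8.4e-08). Ddx4, the germ cell RNA helicase Vasa (chromosome 13, 112598333 to 112652310), went from 127 ± 27.6 to 36.5 ± 3.17 CPM (-1.81 ± 0.17), and Dazl, a germ cell translation factor (chromosome 17, 50279393 to 50293620), from 433 ± 78.0 to 159 ± 19.4 CPM (-1.44 ± 0.15). Stra8, the retinoic acid target needed for meiotic entry (chromosome 6, 34920960 to 34939342), went from 59.6 ± 15.2 to 19.3 ± 0.84 CPM (-1.63 ± 0.20). Kit itself, the sort marker, was at 994 ± 78.5 and 1035 ± 32.7 CPM (0.06 ± 0.10, not past the test). Its counts come from a pair of transcript entries with near-identical counts and so may hold some reads more than once.

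This comparison asked which genes differ between the libraries labelled dKO and control in the cKit+ population. Of 14907 genes tested, 4259 changed, 1965 higher and 2294 lower, and 1488 of these changed at least 2-fold, 506 higher and 982 lower (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The split moved with the scaling: 1278 were higher and 3007 lower with library totals alone, and 12225 and 64 after scaling on germ cell genes. With limma on the deposited RPKM values, which changes the test and the values as well, 459 were higher and 3990 lower. Fitted on only the 4 cKit libraries 3148 genes changed, and on only the 4 Thy1 libraries 870. The gap between 4259 calls in cKit and 93 in Thy1 therefore depends on pooling the spread over all groups. Among called genes at a mean log2 CPM of at least 3, with the groups not overlapping, the largest rises were in Nrg1, a neuregulin ligand (2.54 ± 0.34), Des, the muscle filament desmin (2.46 ± 0.37), Crispld1 (2.35 ± 0.32), Ddit4, an inhibitor of mTOR signalling (1.95 ± 0.24), and Creb5 (1.84 ± 0.29). Hmha1, Fmo1, Abcb5, Dtx1 and Pcdhgb4 rose by 1.68 to 1.74, with Pcdhgb4 uncertain because the protocadherin gamma genes share exons. Within these limits the largest falls were in Zkscan2 (-3.13 ± 0.34), Sall4, Aifm3 (-2.90 ± 0.32), Frmpd1 (-2.78 ± 0.34), Prtg (-2.75 ± 0.19), Ascl2 (-2.72 ± 0.29), the transposon silencing gene Morc1 (-2.70 ± 0.20), the piRNA factor Tdrkh (-2.58 ± 0.20), Ugt8a (-2.54 ± 0.30) and Dab1 (-2.44 ± 0.30). Zbtb16 (-1.21), Gata4 (0.84 ± 0.10) and Wt1 (0.97) changed, and Gfra1 (0.59) did not pass. Cdkn2a, a Polycomb target, had 0 counts in both dKO libraries against 21 in control, 4.56-fold lower against a floor of 3 counts over the group. Those 21 counts were only 1.08 CPM pooled over the control libraries, so this fold is uncertain.

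Germ cell lists fell as sets. In the core germ cell list 15 of 22 members fell, 0 rose and 7 did not pass (median -1.67; 16 lower adjusted over the list alone), among them Mael (-1.71 ± 0.15), Stk31 (-1.97 ± 0.18) and Taf7l (-1.87 ± 0.17). In the piRNA and germ granule list 18 of 22 fell (median -1.62; also 18 adjusted over the list alone), with Piwil2, a PIWI protein, at -2.08 ± 0.17. The differentiating list had 9 of 14 lower (median -1.43; also 9 adjusted over the list alone), including Sohlh1 (-2.29 ± 0.28), Crabp1 (-1.83 ± 0.24) and the DNA methyltransferase Dnmt3b (-1.69 ± 0.16). The meiotic list had 20 of 35 lower (median -0.93; 21 adjusted over the list alone), including the synaptonemal complex genes Syce1 (-1.73 ± 0.19) and Syce2 (-1.59 ± 0.14). Camera adjusted p was 4.2e-17, 8.7e-17, 5.0e-07 and 7.6e-11 in that order, and for each the adjusted p = 0.13 with an estimated correlation. After scaling on the core and piRNA lists their own medians were -0.08 and -0.04 by construction, and those of the differentiating and meiotic lists turned to 0.19 and 0.66. The undifferentiated list moved both ways: 6 of 30 fell, including Lin28a (-1.87 ± 0.17) and Mcam (-1.62 ± 0.14), and 3 rose, including Etv5, a GDNF-responsive factor (1.32 ± 0.14; median -0.18, 3 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.061).

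Cell cycle genes fell too. Of the S phase list 21 of 26 fell (median -0.95; also 21 adjusted over the list alone), among them the replication helicase subunits Mcm6 (-1.32 ± 0.14) and Mcm7 (-1.26 ± 0.14). Of the G2 and M phase list 23 of 25 fell (median -1.05; 24 adjusted over the list alone), with Cenpf at -1.78 ± 0.14 and the checkpoint kinase Bub1 at -1.75 ± 0.15. Camera gave adjusted p = 1.8e-13 and 4.7e-23, with an adjusted p = 0.13 for both with an estimated correlation. Germ cell scaling turned both medians positive (0.69 and 0.57). The CDK inhibitor and p53 list went both ways, 8 higher and 6 lower of 23 (the same numbers adjusted over the list alone), with Cdkn1c at 1.06 ± 0.16 and Btg2 at 0.77 ± 0.12. Its median was 0.39 and its mean -0.30 (camera adjusted p = 0.45), and the median was below 0 with RPKM values and without cKit dKO replicate 2.

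Somatic cell markers rose in the same cKit libraries. The peritubular and stromal list had 14 of 21 higher and 1 lower (median 0.77; adjusted over the list alone 15 and 1; camera adjusted p = 6.2e-08, and adjusted p = 0.23 with an estimated correlation), including the collagen Col1a1 (1.31 ± 0.16), Pdgfra (1.08 ± 0.13) and Nr2f2 (1.07 ± 0.12). The Sertoli list had 10 of 26 higher (median 0.80; 17 adjusted over the list alone), with Gata4 and Sox8 (1.49 ± 0.35). The endothelial list had 7 of 15 higher (median 0.94; 9 adjusted over the list alone), with Cdh5 at 1.01 ± 0.10 and Kdr at 1.502 ± 0.34. Camera adjusted p for these was 1.3e-05 and 2.5e-04, with an adjusted p = 0.13 for both with an estimated correlation. The Leydig list had 7 of 13 higher and 1 lower (median 0.52; adjusted over the list alone 8 and 1; camera adjusted p = 0.0029, and adjusted p = 0.32 with an estimated correlation), with Hsd3b1 at 0.57 ± 0.11. Of 8 mast cell genes 2 rose, Tpsb2 (1.13 ± 0.32) and Cpa3 (0.93 ± 0.29; also 2 adjusted over the list alone; camera adjusted p = 0.061), calls lost without cKit control replicate 1 or cKit dKO replicate 1. The mast cell list passed camera in 8 of 11 other settings, but not with RLE size factors or without either of these libraries. Of 17 macrophage genes 0 passed (also 0 adjusted over the list alone, camera adjusted p = 0.41). Their median was 0.38, and below 0 with RPKM values, without cKit control replicate 1 (-0.13) and without cKit dKO replicate 2 (-0.65). Without cKit control replicate 2 or cKit dKO replicate 1 it was 1.01 and 0.84, and the list passed camera upward.

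Developmental and signalling lists were higher as well. After germ cell scaling the Hox and transcription factor medians were 2.46 and 2.11, against 2.43, 2.41 and 2.58 in the Sertoli, stromal and endothelial lists. The transcription factor list shares Gata4, Wt1, Sox9, Nr2f2 and Sox18 with those lists. A larger share of somatic RNA therefore cannot be told apart from a rise within germ cells. Of 57 somatic transcription factors 19 rose and 5 fell (the same numbers adjusted over the list alone; median 0.53), led by Lhx9 (1.54 ± 0.16), Prrx1 (1.56 ± 0.18) and Osr1 (1.25 ± 0.14), which are mesenchymal and gonadal factors. Of 29 Hox genes 7 rose (also 7 adjusted over the list alone; median 0.86), including Hoxd9 (0.82 ± 0.17) and Hoxd8 (0.74 ± 0.17). Camera adjusted p was 0.0023 and 0.017, with an adjusted p = 0.13 for both with an estimated correlation. The Hox list did not pass without cKit control replicate 2 or cKit dKO replicate 2. Imprinted genes had 14 of 27 higher and 1 lower (median 0.60; adjusted over the list alone 16 and 2; camera adjusted p = 5.0e-07, and adjusted p = 0.13 with an estimated correlation). Among them were the fetal growth genes Igf2 (1.002 ± 0.10) and Dlk1 (1.25 ± 0.11) and, lower, Ascl2. Immediate early and heat shock genes had 16 of 24 higher and 1 lower (median 0.64; adjusted over the list alone 18 and 1; camera adjusted p = 1.2e-05, and adjusted p = 0.32 with an estimated correlation). Examples are Hspa1a (1.26 ± 0.21) and Egr1 (0.69 ± 0.12). The WNT, BMP, FGF and hedgehog list had 6 of 23 higher (median 0.55; 9 adjusted over the list alone; camera adjusted p = 0.025, and adjusted p = 0.26 with an estimated correlation). They include the WNT antagonists Sfrp1 (0.76 ± 0.13) and Sfrp2 (0.94 ± 0.17). This list did not pass without cKit control replicate 2 (camera adjusted p = 0.061).

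Chromatin genes changed in both directions. Of 22 PRC1 subunits 6 fell, including Pcgf5 (-2.02 ± 0.19), Cbx2 (-1.84 ± 0.19), L3mbtl2 (-1.43 ± 0.19) and Bmi1 (-0.85 ± 0.13), and 2 rose (median -0.28; 3 higher and 6 lower adjusted over the list alone). Of 11 PRC2 subunits 4 fell and 1 rose (median -0.32; 5 lower and 1 higher adjusted over the list alone), with Mtf2 at -0.98 ± 0.14 and Jarid2 at -0.88 ± 0.13. Of 7 DNA methylation enzymes 3 fell, the maintenance pair Dnmt1 (-1.03 ± 0.11) and Uhrf1 (-1.07 ± 0.15) and Dnmt3b, and 2 rose, including Tet1 (1.02 ± 0.16; the same numbers adjusted over the list alone, median -0.06). None of these lists passed camera (adjusted p = 0.066, 0.067 and 0.10), and all of their medians turned positive after germ cell scaling. Without cKit control replicate 1 the count of changed genes in cKit was 2386, and without replicate 1 of both control groups 1977.

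**Figure D2:**
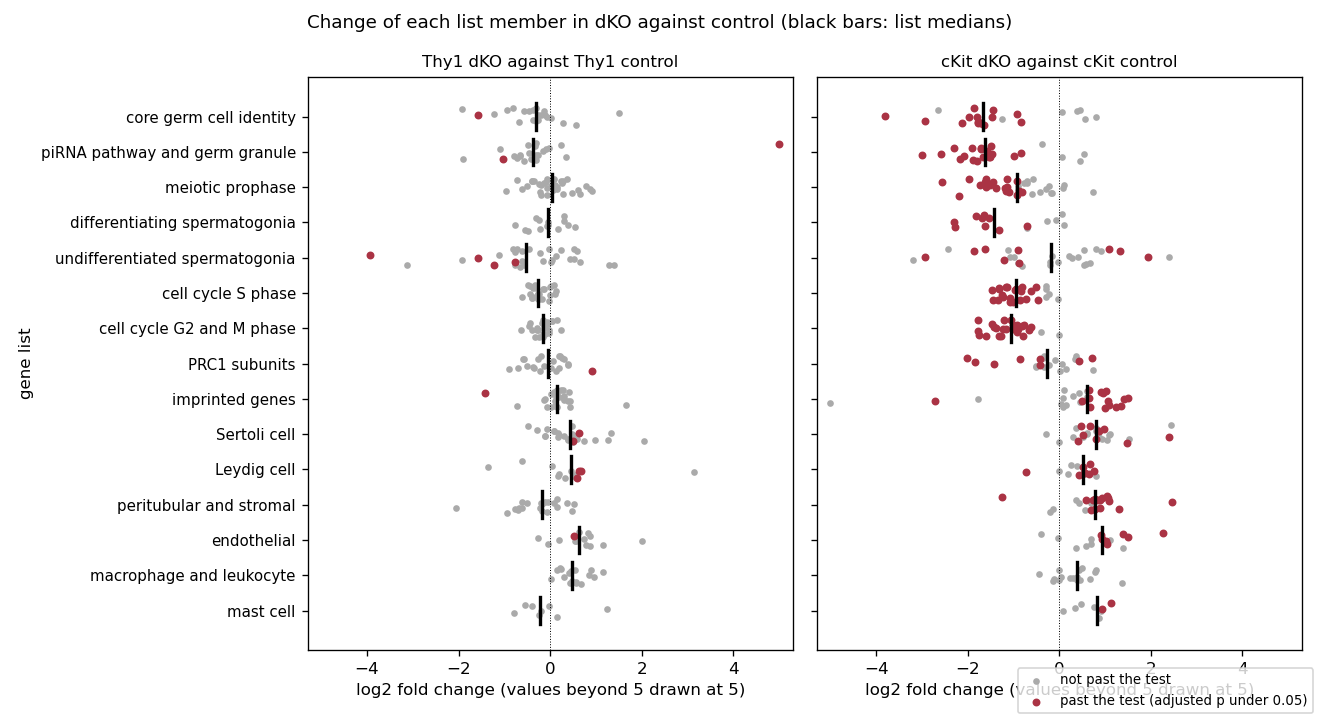
The log2 fold change of each tested list member in the libraries labelled dKO against control, in Thy1 (left) and cKit (right); red points passed edgeR's test at an adjusted p of 0.05 and black bars are list medians. In cKit the core germ cell and piRNA medians lie at -1.67 and -1.62 and the stromal and endothelial medians at 0.77 and 0.94.

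The genes that changed in Thy1 mostly changed the same way in cKit. Of the 54 genes higher in Thy1 dKO 41 were also higher in cKit dKO, where independent lists would share 7.12 (one-sided Fisher's exact p = 1.1e-25). Of the 39 lower genes 27 were also lower, against 6.00 (one-sided Fisher's exact p = 5.8e-14). Both p-values treat genes as independent, which they are not, and do not measure the spread between samples. Sall4, Lin28a, Sall1, Ascl2 and Pramef12 were lower in both, and Stk32a, Gata4, Bmp5, Cdh5 and Bcor were higher in both. In cKit Stk32a rose by 1.51 and Bmp5 by 1.18, while Nefm, at 0.89, did not pass. Of the genes called in Thy1, 1 moved the opposite way past the test in cKit. Across all genes, which are not independent replicates, the log2 fold changes of both comparisons had Pearson's r = 0.30 and Spearman's rho = 0.38, with a covariance of 0.15 against 9.0e-04 in 20 simulations of unchanged groups. The 68 shared calls were 4 and 8 without Thy1 control replicate 1 or 2, 1 without Thy1 dKO replicate 1 or 2, and 244 and 264 without cKit dKO replicate 1 or 2.

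**Figure D3:**
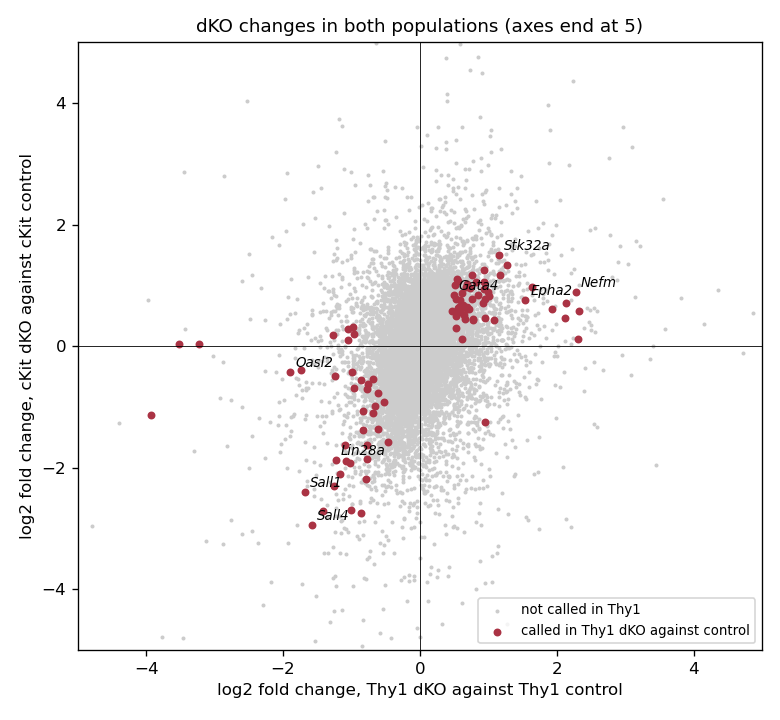
The log2 fold change of each gene in the libraries labelled dKO against control, in Thy1 (horizontal) and cKit (vertical); red points are genes called in Thy1, grey points all others, and 68 genes, 2 of them called in Thy1, lie outside the axes. Of the 93 called genes 85 have the same sign in cKit.

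Between the control libraries, cKit+ cells carried less RNA of stem cell and stromal genes and more of Leydig and mast cell genes than Thy1+ cells. Gfra1, the GDNF co-receptor of spermatogonial stem cells (chromosome 19, 58236692 to 58454466), was at 1.70 ± 0.42 CPM in cKit control and 35.0 ± 6.58 in Thy1 control (SD, n = 2), a log2 fold change of -4.32 ± 0.29 (edgeR adjusted p = 6.5e-08). Its partner receptor Ret fell by 4.08 on the log2 scale (SE 0.21), and Zbtb16 (PLZF) by 1.37 (SE 0.13). Stra8 rose by 0.96 ± 0.19. Hsd3b1 stood at 7702 ± 498 CPM in cKit control against 1774 ± 188 in Thy1 control (2.12 ± 0.11). Kit (1.68) and Thy1 (-4.86) differed as the genes the cells were sorted by, which is no finding.

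In this comparison of the populations among the libraries labelled control, 2939 genes changed, 1410 higher and 1529 lower in cKit (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 1481 at least 2-fold. With limma on the deposited RPKM values 73.0% of the changed genes were higher, against 48.0%. Undifferentiated markers had 21 of 30 lower (median -1.30; 22 adjusted over the list alone; camera adjusted p = 2.2e-17, and adjusted p = 0.079 with an estimated correlation). The stromal list had 20 of 21 lower (median -2.56; 21 adjusted over the list alone; camera adjusted p = 9.0e-40, and adjusted p = 0.089 with an estimated correlation), including Dcn (-2.58 ± 0.12) and Lum (-4.71 ± 0.27). It shares Thy1 and Pdgfra with the undifferentiated list. Among called genes at a mean log2 CPM of at least 3, with the groups not overlapping, the largest falls beside Lum and Gfra1 included Col6a5 (-5.37 ± 0.37), Mfap5 (-4.66 ± 0.32), Postn (-4.65 ± 0.24), Fmod (-4.36 ± 0.39) and Rgs5 (-4.44 ± 0.19). Gpr133, Pgm5 and S100a6 fell by 4.25 to 4.66. Macrophage genes had 12 of 17 lower (median -1.80; 16 adjusted over the list alone; camera adjusted p = 3.2e-08, and adjusted p = 0.34 with an estimated correlation). Imprinted genes had 12 of 27 lower and 3 higher (median -0.75; the same numbers adjusted over the list alone; camera adjusted p = 7.9e-09, and adjusted p = 0.16 with an estimated correlation). Somatic transcription factors had 16 of 57 lower and 3 higher (median -0.68; 18 and 3 adjusted over the list alone; camera adjusted p = 0.0014, and adjusted p = 0.17 with an estimated correlation).

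Higher in control cKit were 11 of 13 Leydig genes (median 1.89; also 11 adjusted over the list alone; camera adjusted p = 9.4e-30, and adjusted p = 0.079 with an estimated correlation), including Lhcgr (2.08 ± 0.13) and Cyp11a1 (1.89 ± 0.13). So were 6 of 8 mast cell genes (median 2.58; also 6 adjusted over the list alone; camera adjusted p = 1.3e-05, and adjusted p = 0.18 with an estimated correlation), including the mast cell proteases Cpa3 (2.85 ± 0.34) and Mcpt4 (2.70 ± 0.35). The Sertoli list had 6 of 26 higher and 2 lower (median 0.32; 7 and 2 adjusted over the list alone; camera adjusted p = 0.0093, and adjusted p = 0.27 with an estimated correlation), with Clu at 1.68 ± 0.12. Within the limits given for the falls, Bpifb4 (2.86 ± 0.35), Tmprss13 (2.82 ± 0.40), Ankrd63 (2.80 ± 0.36) and Slc47a1 (2.75 ± 0.29) led the other rises, and Npffr2, Atp2b3, Nppc and Dsc2 rose by 2.43 to 2.67. The differentiating list did not pass camera (4 of 14 higher and 1 lower, 4 and 2 adjusted over the list alone; median 0.39; camera adjusted p = 0.093), with Dmrtb1 at 1.03 ± 0.21 and Ccnd2 at -0.95 ± 0.12. Its median was below 0 without cKit control replicate 1. The count of changed genes was 1717 without Thy1 control replicate 1 and 1821 without replicate 2. The record numbers of the libraries fall in ranges that follow the population, so a batch and the population cannot be told apart.

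Between the libraries labelled dKO, the populations differed in 5190 genes, 2202 higher and 2988 lower in cKit (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Germ cell lists were lower here in cKit: 14 of 22 core members fell and 1, Kit, rose (median -1.60), 17 of 22 piRNA members fell (median -1.53), and 26 of 35 meiotic members fell (median -1.35), with Stk31 at -2.35 ± 0.18, Dazl at -1.90 ± 0.15 and Smc1b at -1.90 ± 0.16. Adjusted over the list alone, 15, 20 and 28 were lower in these lists. Camera adjusted p was 6.9e-11, 7.3e-11 and 6.9e-11, with an adjusted p = 0.19 for each with an estimated correlation. In the control libraries these 3 lists did not pass camera (medians -0.40, -0.15 and -0.21; adjusted p = 0.18, 0.16 and 0.31), but without cKit control replicate 1 the core and piRNA lists passed it, also lower in cKit. The undifferentiated list (18 of 30 lower and 1 higher, 21 and 1 adjusted over the list alone; median -1.77), the differentiating list (7 of 14 lower and 1 higher, also adjusted over the list alone; median -1.05), the S phase list (20 of 26 lower, 22 adjusted over the list alone; median -0.74) and the G2 and M phase list (23 of 25 lower, 24 adjusted over the list alone; median -0.88) also passed camera, with adjusted p = 6.9e-11, 0.020, 2.2e-07 and 1.1e-12. Their adjusted p = 0.15, 0.32, 0.28 and 0.19 with an estimated correlation. The differentiating list did not pass without cKit dKO replicate 1.

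Among called genes at a mean log2 CPM of at least 3, with the groups not overlapping, large differences between the dKO populations were in Cpa3 (3.99 ± 0.35), Mcpt4 (3.70 ± 0.36), Espn (2.86 ± 0.30), Vsnl1 (2.64 ± 0.16) and Wnt6 (2.47 ± 0.25), all higher in cKit. Lower in cKit were Col6a5 (-4.89 ± 0.36), Nefm (-4.70 ± 0.25), Rgs5 (-4.31 ± 0.19), Gfra1 (-4.26 ± 0.29), Cbr2 (-3.94 ± 0.27) and Ret (-3.80 ± 0.21). Nppc, Cdhr5, Rab13, Slc25a35 and Slc25a34 were higher by 2.41 to 2.52, and Prkg1, Gpr133 and Sulf1 were at -3.73 to -3.66. Leydig (12 of 13 higher, also adjusted over the list alone; median 1.81), mast cell (6 of 8 higher, also adjusted over the list alone; median 3.50), Sertoli (9 of 26 higher and 1 lower, also adjusted over the list alone; median 0.71) and immediate early genes (14 of 24 higher and 1 lower, 17 and 1 adjusted over the list alone; median 0.76) passed camera upward with adjusted p = 3.7e-25, 2.9e-08, 5.4e-06 and 5.7e-08. Their adjusted p = 0.15, 0.15, 0.15 and 0.32 with an estimated correlation. Stromal (15 of 21 lower, 15 lower and 3 higher adjusted over the list alone; median -1.40) and macrophage genes (14 of 17 lower, 17 adjusted over the list alone; median -2.08) passed downward with camera adjusted p = 3.4e-09 and 1.0e-07, and adjusted p = 0.27 and 0.32 with an estimated correlation. With library totals alone 30.5% of the changed genes were higher, against 42.4%. The count was 3101 and 3368 without Thy1 dKO replicate 1 or 2.

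Set against the difference between the control populations, genes that rose in the Thy1 libraries labelled dKO were often genes higher in control cKit. Tmprss13, Npffr2 and Bcor were among the 33 of 54 higher calls that were also higher in control cKit than in control Thy1 (5.11 for independent lists). Lin28a, Mcam and Sall4 were among the 17 of 39 lower calls that were also lower (4.0 for independent lists). For cKit dKO, 407 of the 1965 higher calls were higher in control cKit (185.9 for independent lists) and 511 were lower in control cKit (201.5), including Dcn, Col1a1 and Dlk1. By contrast 117 of the 2294 lower calls were lower (235.3) and 124 higher (217.0), including Stra8 and Dnmt3b. The comparisons share control libraries. Libraries simulated with no gene changed in any group gave 0.20 calls shared in the same direction for Thy1 and 0.15 in opposite directions for cKit. With no gene changed few calls could arise, so these counts do not measure what the shared controls add. The covariance of the log2 fold changes was 0.14 for Thy1 (0.084 simulated, a difference of 0.052) and -0.14 for cKit (-0.080 simulated, a difference of -0.063), with Pearson's r = 0.26 and -0.17 (0.50 and -0.48 simulated). The controls could not be split, with 2 libraries per group, so part of the shared calls beyond independent lists may come from the shared controls.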

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

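The test of gene lists on the difference of effects, and all tests of explanations but those on transcript length and on single libraries, were chosen after the results had been seen. The effect labelled dKO differed between the populations: 883 genes passed edgeR's quasi-likelihood test of the difference (cKit minus Thy1, Benjamini-Hochberg adjusted), 278 higher and 605 lower. The higher share of 31.5% was 15.1% with library totals, 3.34% with limma on RPKM values and 43.5% with DESeq2. Germ cell scaling reversed the split, with 8160 higher and 36 lower (99.6% higher), and moved the median of all genes by 1.24. Among called genes at a mean log2 CPM of at least 3 the largest positive differences (log2) picked by the naming rule were in Flad1 (4.42), Ddit4 (2.72), Des (2.65), Crispld1 (2.23), Fmo1 (1.95), Gstm6 (1.81), Dpt (1.80), Ifitm1 (1.77), Pcdhgb4 (1.74) and Prrx1 (1.73). Flad1 had 732 counts in cKit dKO replicate 1 and 30 in replicate 2, so its value rests on a single library. The largest negative ones within that limit were in the meiotic gene Mei1 (-3.11), Zkscan2 (-2.63), Hid1 (-2.57), the piRNA factors Tdrd12 (-2.53) and Tdrkh (-2.43), Ugt8a (-2.50), Aifm3 (-2.49), Bnc1 (-2.30), Abcc8 (-2.23) and the germ cell helicase Ddx43 (-2.22). Stra8 (-1.40), Dazl (-1.33) and Ddx4 (-1.499) also fell more in cKit. The count was 297 and 526 without Thy1 control replicate 1 or 2, 219 and 378 without Thy1 dKO replicate 1 or 2, and 367 without cKit control replicate 1.

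By list, the median difference of effects was negative for differentiating spermatogonia (-1.29; 7 of 14 members past the test), meiotic prophase (-1.21; 13 of 35), the piRNA pathway (-1.22; 10 of 22), core germ cell identity (-1.34; 12 of 22), S phase (-0.73; 6 of 26) and G2 and M phase (-0.86; 17 of 25). It was positive for the Sertoli (0.30; 0 of 26), stromal (0.92; 10 of 21), mast cell (0.94; 0 of 8), imprinted (0.51; 7 of 27) and immediate early lists (0.53; 3 of 24). All 11 passed camera (adjusted p = 2.8e-21 to 0.024), and 0 of 25 lists passed with an estimated correlation (smallest adjusted p = 0.18). The mast cell list did not pass camera without 4 of the libraries in turn, and the Sertoli list not without cKit dKO replicate 1. After germ cell scaling the S phase and G2 and M phase medians were positive. That scaling sets the core and piRNA medians near 0 by construction.

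Germ cell lists were lower in the cKit libraries labelled dKO than in control, which could come from a smaller share of germ cell RNA, from a loss of long transcripts, or from lower expression in the germ cells that the labels' genotype would give. The tables argue against length as the cause: the 21 shorter core and piRNA members had a median log2 change of -1.54 (bootstrap SE over members 0.16), against -1.68 (SE 0.19) for the 20 longer ones. Lengths were inferred from the ratio of counts to RPKM. After scaling on these lists 11 of 41 members still passed the test, so a single common factor does not account for every member. Sall4, Tdrkh and Piwil1 were lower than the rest. Kit, Sycp3, Mybl1, Tdrd5, Fkbp6, Dppa3, Prdm1 and Zfp42 were higher than the rest, and Kit, the sort marker, had not passed before that scaling. A smaller share would lower all members alike only if germ cells alone express them, which was not tested. These members therefore do not decide the question. A smaller share stays open, as the test on other cell types depends on single libraries. Medians of the Sertoli, Leydig, stromal, endothelial, macrophage and mast cell lists were 0.38 to 0.94 with a range of 0.56 (permutation p = 0.0515). That permutation reassigns genes among the lists, treats them as independent and does not measure the spread between samples. The macrophage median was -0.13 without cKit control replicate 1 and -0.65 without cKit dKO replicate 2, where the range was 1.16 and 1.65. It was 1.01 and 0.84 without cKit control replicate 2 or cKit dKO replicate 1, where the range was 0.64 and 0.42. A change of germ cell expression, and RNA quality or composition apart from length, also stay open and untested. Malat1 stood at 3.75% and 2.56% of counts in cKit dKO against 1.68% and 2.10% in control. Entries at 0 were 31.6% and 33.1% against 28.3% and 30.0%. The cKit dKO libraries also had the fewest counts (6763908 and 6798003, against 10976869 and 7858587 in control). Fewer counts alone raise the share of entries at 0.

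Genes called lower in the Thy1 libraries labelled dKO may reflect fewer germ cells, a single library, or a change within the cells. Both Sall4 and Lin28a met the rule that the groups do not overlap, so leaving out a library could not reverse their sign. The sizes still argue against a single library for these genes. Leaving out each of the 4 Thy1 libraries in turn gave -1.64 to -1.51 for Sall4 and -1.34 to -1.13 for Lin28a. Lin28a did not pass the test without either Thy1 dKO library. A smaller germ cell share stays open: 39 genes picked as lower in 1 control and 1 dKO library had, in the other 2 libraries after scaling on the germ cell lists, medians of -0.42, -0.38, -0.12 and -0.0934 over the 4 splits, and the latter pair lay within 2 standard errors of 0. After that scaling with all libraries 4 of the 39 called genes were still called, among them Sall4 (-1.19 ± 0.26; edgeR adjusted p = 0.014), while Lin28a was not (-0.85 ± 0.26 against -1.23 ± 0.15 before; edgeR adjusted p = 0.077), with a smaller fold and a larger standard error. The genotype named by the labels also stays open.

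Leydig and mast cell markers were higher in control cKit than in control Thy1, which may come from cells of these types that carry Kit and so pass the cKit sort, or from a batch. Members of these lists had a median log2 change 2.52 above that of Sertoli, endothelial and macrophage members (1.89 against -0.63, 20 and 57 members), which restates the pattern and decides nothing about carried-over cells. Batch and population cannot be told apart, because 0 record ranges hold libraries of both populations. A difference between the populations of spermatogonia was not tested and stays open as well.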

How the results depend on the processing

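Germ cell scaling, leaving out Rn45s and leaving out replicate 1 of both control groups were chosen after seeing the data; the other alternatives were planned. Named genes were run with RLE size factors, no filter, DESeq2, the replicate block and each library left out. Of 459 results for them beside Ring1 and Rnf2 in dKO, 358 were called, of which 275 kept their call throughout and 83 lost it in at least 1 setting. Of the 101 others 34 gained a call, and 0 results changed direction with a call on either side, while changes without a call could change sign. Germ cell scaling, not among these settings, changed the sign of 1881 of the 4259 genes called in cKit dKO. Entries not summed, RPKM values and limma-voom were not among them either. With entries not summed 0 of the 93 calls in Thy1 dKO were kept, and with RPKM and a pseudocount of 0.1 only 6 were. For the genes changed in Thy1 dKO (93), the count was 563 with no filter, 330 with DESeq2 (86 of the 93 shared), 188 with limma-voom, 24 and 6 with RPKM and a pseudocount of 1 or 0.1, 35 at 2-fold, 870 with only the 4 Thy1 libraries (93 shared), 143 with germ cell scaling, 7 without replicate 1 of both control groups, and 0 with entries not summed (1785 at an unadjusted p under 0.05). In cKit dKO (4259) it was 1488 at 2-fold, 2785 with entries not summed, 12289 with germ cell scaling and 1977 without replicate 1 of both control groups. Between controls (2939) it was 1481 at 2-fold and 1701 with entries not summed, between dKO groups (5190) 2437 at 2-fold, and for the difference of effects (883) 1490 with no filter, 501 at 2-fold, 25 with entries not summed and 8196 with germ cell scaling. A 2-fold minimum lowers a count by construction, and for the other settings the cause was not tested. Leaving out single libraries gave 3 to 400, 2386 to 3972, 1717 to 3575, 3101 to 5245 and 219 to 1268 changed genes in these comparisons, and -0.20 to 1.34 for Ring1 in cKit dKO and -0.17 to 0.82 in Thy1 dKO. The 68 shared calls of Thy1 and cKit were 246 with DESeq2, 484 with only the libraries compared, and 1 to 264 with a library left out. With an estimated correlation 0 lists passed in each comparison, and fry passed 0 in Thy1 dKO, 13 between controls and 22 between dKO groups. The replicate number as a block gave 157 genes in Thy1 dKO and no count beyond 1.5 times elsewhere. As a block within each population it gave 85 in Thy1 dKO and 3988 in cKit dKO. Replicate deviations correlated at -0.045 to 0.052 between groups, so same-numbered libraries showed no shared deviation. Whether they were prepared together is not shown by this. Relative to the main scaling the median of all genes moved by -0.14 with library totals in cKit dKO, by -0.29 in cKit dKO and 0.20 between controls with RPKM (pseudocount 1), and by 0.38 (Thy1) and 1.62 (cKit) with germ cell scaling. At this depth a 2-fold change was recovered for 55% of simulated genes in Thy1 and 56% in cKit. Far fewer genes changed in the simulation than were called in cKit dKO. The adjusted threshold depends on how many genes change, so recovery in the data may differ. A gene that did not pass is still not shown to be unchanged.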

Other observations

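Gene families grouped by symbol, chosen after seeing the data, showed further groups in the cKit libraries labelled dKO. Collagen genes had 23 of 43 members higher and 0 lower (median log2 0.74; camera adjusted p = 7.7e-08 over 131 families, and adjusted p = 0.59 with an estimated correlation). Protocadherin beta genes had 6 of 21 higher (median 0.88) and protocadherin gamma genes 11 of 22 (median 0.85), with camera adjusted p = 0.026 and 7.9e-05, and adjusted p = 0.59 and 0.48 with an estimated correlation; gamma genes share exons, so their counts are uncertain. Nucleoporin genes (Nup) had 16 of 22 lower and 1 higher (median -0.71), kinesins (Kif) 18 of 35 lower and 2 higher (median -0.65), TAF genes 13 of 23 lower (median -0.60) and testis-expressed genes (Tex) 12 of 17 lower (median -1.11). Their camera adjusted p was 9.2e-08, 3.1e-06, 3.1e-06 and 7.7e-08, with an adjusted p = 0.48 for each with an estimated correlation.

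The remaining lists were late spermatogenesis, oocyte and granulosa, T cell and erythroid genes. In cKit dKO, 2 of 12 late spermatogenesis genes fell, Pdha2 (-1.48 ± 0.35) and Clgn (-1.23 ± 0.37), calls lost without cKit dKO replicate 1 (median -0.33; also 2 adjusted over the list alone; camera adjusted p = 0.45). Of 16 oocyte and granulosa genes 3 fell, the NLRP gene Nlrp4f, with 0 counts in both cKit dKO libraries and at least 11.3-fold lower, Lhx8 (-2.33 ± 0.47) and Nlrp14 (-2.51 ± 0.77), and Kitl rose (0.67 ± 0.12; the same numbers adjusted over the list alone). That list's median was 0.04 and its mean -0.58 (camera adjusted p = 0.82), and the median was below 0 with library totals, with RPKM values and without either cKit dKO library. Of 6 T cell genes 1 fell, Cd3e (-2.13 ± 0.60; also 1 adjusted over the list alone), while the list median was 0.86, or 0.39 with the bound for a member at 0 counts (camera adjusted p = 0.72). In Thy1 dKO 1 gene of these lists passed, Nobox, an oocyte homeobox gene (2.13 ± 0.38), a call lost without any 1 of the 4 Thy1 libraries. Only 1 erythroid gene was tested, Alas2 (0.59 in Thy1 dKO and 0.55 in cKit dKO, not past the test).

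Some library measures differed between the groups and also within them. Malat1, a nuclear long noncoding RNA, took 3.75% and 2.56% of the counts in cKit dKO, 1.68% and 2.10% in cKit control, and 1.18% to 1.30% in the Thy1 libraries. Summed over the macrophage list, CPM were 193 and 424 in the cKit controls and 176 and 595 in the cKit dKO libraries, so replicates differed more than the groups did. The stromal list summed to 19623 CPM in Thy1 control replicate 1 and 14743 in replicate 2.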
